A study of Mus musculus with 6 samples.

How the data were processed

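The samples were glomeruli of 3 pools from BXSB/MpJ-Yaa and 3 pools from BXSB/MpJ-Yaa+ male mice aged 4 months, each pool holding 2 of the 6 glomerular populations of its strain. Total RNA was checked for integrity, amplified and labelled with Cy3, per the labels' protocols, and hybridised to 1-colour Agilent whole-genome mouse arrays, 1 array per pool. The deposited files are scanner output in linear signal intensity. Per the file headers the authors' spot signals came from Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes name version 9.5.3. The processed signal intensity had been background-subtracted and detrended within each array, with dim spots replaced by surrogate values, and had not been normalized between arrays, per the file headers and the values. Where dim spots carry surrogates, differences between groups near the background rest on those values. Probe coordinates are on mm9, per the file headers.

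Arrays were grouped by title, description and genotype, which gave the same strain in each sample. The source name gave the other strain in every sample. The genes of the X segment copied onto the Yaa chromosome were used to check the labels. All 6 arrays lay on 1 slide from 1 scan. Controls filled one column of the slide and Yaa samples the other, so that slide column and strain cannot be told apart, and the slide row ran with the replicate number.

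For each array, control spots (3671 of them) and spots with an outlier flag (121 to 166 per array) were left out, log2 of the processed signal was taken and the array's 75th percentile subtracted. Spots of 1 probe were averaged, which left 55681 probes. A probe was kept where at least a share of 0.5 of its spots was well above background on all 3 arrays of 1 group or more, which kept 28598 probes. A gene, by the array's gene name, was represented by its kept probe with the highest mean signal, which gave 20716 genes. Of 5577 genes with more than 1 kept probe, none had probes past the test in opposite directions and 132 had some but not all of their probes past it. Current symbols came from a table of RefSeq genes on GRCm38.p6, used for names only, in which 26762 probes matched by accession, 3819 by symbol and 639 by synonym, and 24461 did not match. No probe was saturated.

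Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 4 residual and 2.84 prior degrees of freedom), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All adjusted p-values of genes are from this model. Where a probe was not well above background on any array of a group, the fold is given as a bound. It sets the bright group's mean against the mean of, per array of the dim group, the higher of the lowest signal among probes well above background and the probe's own signal. That lowest signal is an extreme of the array and not a detection limit. A bound is therefore not a guaranteed minimum, and normexp correction gave some of these genes a smaller fold change than their bound. The 26 gene lists, the rule for naming genes, the main model and its alternatives were fixed before the data were examined. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance without comparing them with other genes. Of the lists that camera called, fry did not call those of T cell, B cell and plasma cell, mesangial and distal nephron markers, extracellular matrix and immediate early genes, and of those it did not call fry called the parietal epithelial one (adjusted p = 0.0319). Genes in more than 1 list were few, with 1 or 2 shared by any pair. The text names the 12 largest rises and 12 largest falls past the threshold among genes whose array name is not an accession, clone, predicted gene or receptor segment, every measured gene of the X segment and Toll-like receptor lists, up to 4 members of every other list with the smallest adjusted p, and structural podocyte genes, of which Nphs1 was not measured on enough arrays. Some genes that this rule takes are not reported here.

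Both groups carry replicate numbers 1 to 3. Deviations from the group means over all genes correlated at 0.126, 0.205 and 0.218 for arrays with the same number and at -0.194 to 0.028 for the others. Deviations within a group sum to 0, so higher values for some pairs of arrays bring lower ones for others, and this contrast is partly built in. In an alternative with the replicate number as a block, same-numbered arrays are treated as pairs. The pairing rests on the replicate numbers, which run with the slide rows, and no label states it. Arrays correlated at 0.969 to 0.983 within groups and 0.965 to 0.976 between groups, and the median SD of a gene was 0.154 in controls and 0.245 in Yaa samples.

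A gene's brightest probe was chosen anew in each alternative, which for normexp correction changed it in 2 named genes, Tlr8 and Mid1. The alternatives were quantile normalization, centring on the median, normexp background correction of the mean signal with an offset of 50, no filter on dim probes, only probes above background on all 6 arrays, the mean of a gene's probes, every probe on its own, an intensity trend with robust variances, the replicate block, leaving out each array and an adjusted p of 0.01. The procedure was tested on simulated data for this comparison with 20716 genes. It recovered 31% of genes changed 2-fold and 80% of those changed 4-fold, with 7 false calls among 118. Where no change was simulated it called 0 genes and 0 lists. Each gene was simulated with the same SD in both groups, without surrogate values and after the filter on dim probes. The data have a larger spread in Yaa samples and surrogates at dim spots, so these rates may not hold for them. Genes were simulated independently of each other, so the 0 lists cannot speak for lists whose genes vary together. In the data the estimated correlation within a list reached 0.922 (proximal tubule markers). Figures were drawn with matplotlib 3.10.9.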

Results

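Gene expression was measured in glomeruli, the filtering units of the kidney, of male mice aged 4 months from 2 strains. BXSB/MpJ-Yaa males develop an autoimmune glomerulonephritis and carry on the Y chromosome a duplicated piece of the end of the X chromosome, the Yaa locus. BXSB/MpJ-Yaa+ males carry a normal Y chromosome and served as controls. Glomeruli were isolated by perfusion with magnetic beads, and 6 glomerular populations per strain were pooled 2 by 2, which gave 3 arrays per strain. Each array reported Cy3 signals of 60-base probes. The 75th percentile of the signal ran from 261.2 (control replicate 2) to 432.1 (Yaa replicate 3), and 50.5% (Yaa replicate 1) to 59.8% (Yaa replicate 3) of the spots were well above background. The number of arrays limits the precision of all values below, which are log2 fold changes of Yaa over control ± SE with n = 3 arrays per group unless stated otherwise.

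The first comparison asked whether the arrays carry the genotype that the labels give them, since in every sample the source name gave the other strain while the title, the description and the genotype all gave the same one. Genes of the X segment that is copied onto the Yaa chromosome were higher on the arrays labelled Yaa. Tlr7, a receptor for single-stranded RNA, rose by 0.91 ± 0.12 (adjusted p = 0.00693), from 1.64 ± 0.03 to 2.55 ± 0.06 (log2 signal, SD), with an adjusted p of 0.0504 without control replicate 1, and also 0.0504 with no filter on dim probes. Its neighbour Tlr8 rose by 2.82 ± 0.18 (adjusted p = 0.000552). It was not well above background on any control array, with a bound of 6.29-fold (2.65 on the log2 scale). Normexp background correction gave a smaller log2 fold change, 0.89 on this probe and 1.42 on the gene's other probe, the brighter one after it. Arhgap6, a GTPase-activating protein, rose by 0.99 ± 0.16, Msl3, a chromatin protein, by 0.91 ± 0.16, and Tmsb4x, the actin-binding thymosin beta 4, by 0.73 ± 0.12. Of the 16 listed genes 12 were measured, and 9 rose over all genes tested, none fell and 3 did not pass. Rab9 (0.74 ± 0.13), Trappc2 (0.77 ± 0.14), Gpm6b (0.73 ± 0.14) and Mid1 (1.65 ± 0.32, well above background on 1 of the 3 control arrays) were the others that rose. The 3 that did not pass were Prps2 at 1.01 ± 0.26 (adjusted p = 0.110), Hccs at -0.19 ± 0.21 and Ofd1 at -0.06 ± 0.15. Adjusted over the list alone, 10 genes were higher and none lower. The median of the list was 0.84 (camera adjusted p = 9.40e-13), with adjusted p = 0.0649 with an estimated correlation. The mean log2 signal of the 12 genes was 1.22, 1.18 and 1.14 on control replicates 1 to 3 and 1.97, 2.17 and 2.16 on Yaa replicates 1 to 3.

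On the mm9 assembly, to which the array's probes are placed, the probe of Tlr7 lies on chromosome X from 163742863 to 163742922 and that of Tlr8 from 163680626 to 163680685. An annotation of that assembly was not used here, so the exon or untranslated region under each probe is not given. The other Tlr7 probe above background, from 163743146 to 163743205, differed by 1.32, and the other Tlr8 probe, from 163683356 to 163683415, also not well above background on any control array, was at least 8.57-fold higher. Going toward the end of the chromosome, Gemin8, with a probe starting at 162627693, had a fold change of -0.03, and Gpm6b, with a probe starting at 162826765, was the first gene beyond it that passed the test. Of the 21 genes within 5 Mb of the last X probe 10 rose and none fell, with a median of 0.74 (camera p = 9.86e-14), and p = 0.00123 with an estimated correlation. With normexp correction this median was 0.21. The 21 include the 12 measured segment genes, and with them the 9 that rose, so this is not a separate check. Over the other 726 genes of X the median was -0.10, 20 rose and 9 fell. Without control replicate 1, 2 or 3, 2 of the 9 segment genes stayed past the test each time, and without Yaa replicates 1, 2 and 3 it was 9, 2 and 3. With the replicate number as a block, 4 of the 9 segment genes stayed past the test. The block gave adjusted p = 0.0584 for Tmsb4x, 0.0698 for Gpm6b, 0.0716 for Trappc2, 0.0726 for Rab9 and 0.122 for Mid1, normexp background correction gave 0.472 for Trappc2, whose fold change became 0.19, and 0.840 for Mid1, whose fold change became 0.15 on another probe (0.35 on the same one), the mean of a gene's probes gave 0.460 for Arhgap6, at 0.32, and 0.190 for Mid1, quantile normalization gave 0.0545 for Tmsb4x, and an intensity trend with robust variances gave 0.0788 for Trappc2. With no filter on dim probes 1 of the 9, Tlr8, passed, and besides Tlr7 the adjusted p was 0.0894 for Arhgap6, 0.114 for Tmsb4x, 0.119 for Msl3, 0.131 for Rab9, 0.147 for Mid1, 0.152 for Trappc2 and 0.173 for Gpm6b.

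**Figure D1:**
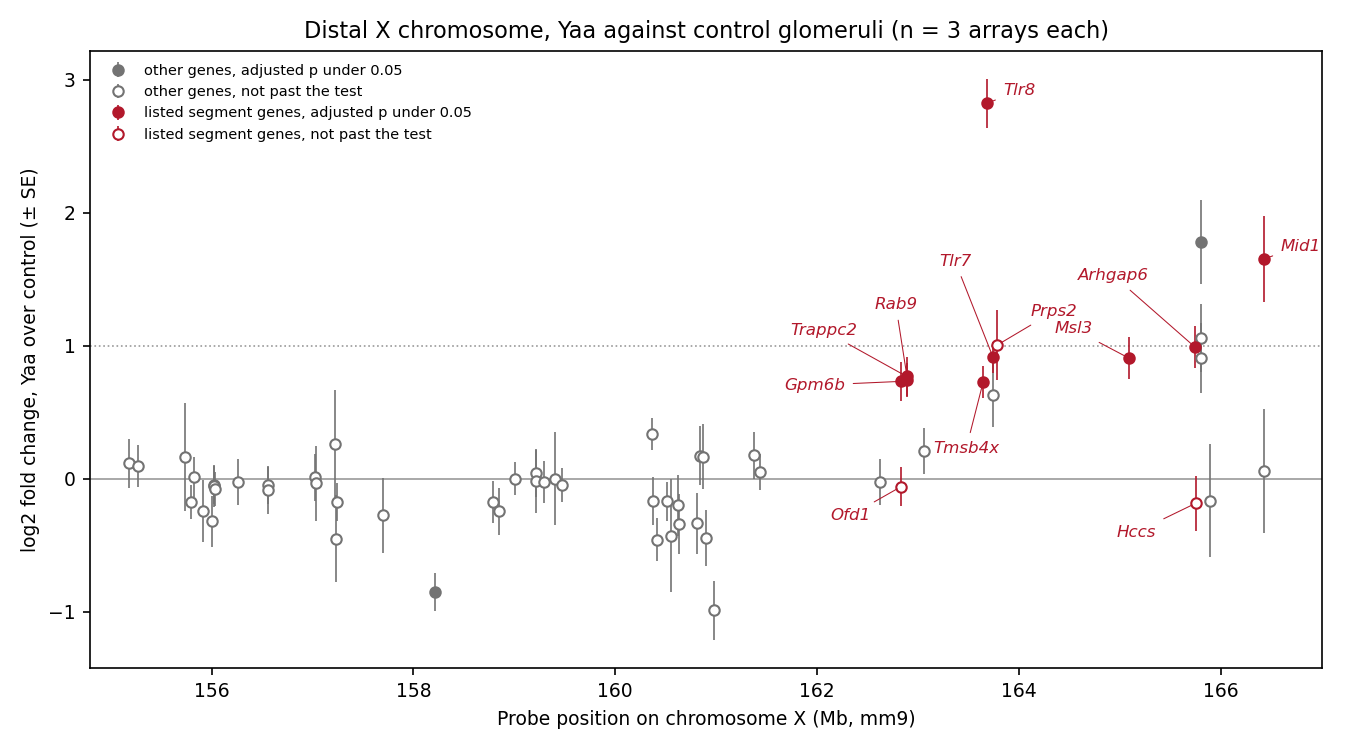
Log2 fold change (Yaa over control, ± SE, n = 3 arrays per group) of each gene tested on distal chromosome X against the start of its probe in Mb on mm9, with listed segment genes in red, other genes in grey and filled points past an adjusted p of 0.05. Segment genes from Gpm6b (0.73) to Mid1 (1.65) lie above 0 apart from Ofd1 (-0.06) and Hccs (-0.19), and Tlr8 (2.82) stands highest; the dotted line marks a log2 fold change of 1.

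The main comparison asked which genes differ between glomeruli of the nephritic strain and of the control strain. Genes of macrophages, complement and chemokine signalling stood among the largest rises. Ms4a7, a membrane protein of macrophages, rose by 7.30 ± 0.35, Adamdec1, a secreted protease of macrophages and dendritic cells, by 7.17 ± 0.45, Rgs1, a regulator of G protein signalling in leukocytes, by 6.95 ± 0.57, and C1qa and C1qc, which encode chains of complement C1q, by 6.40 ± 0.52 and 6.39 ± 0.29. The rises of the formyl peptide receptor Fpr2 (5.73 ± 0.47), the chemokine Ccl4 (5.64 ± 0.62), the Fc receptor Fcgr4 (5.51 ± 0.29), the lectin Clec4b1 (5.32 ± 0.57), Bcl2a1c (5.28 ± 0.50), Cd72 (5.27 ± 0.27) and Ms4a6d (5.20 ± 0.52) completed the 12 largest fitted rises among genes with an established symbol. The largest adjusted p among these 12 was 0.00378. Adamdec1, Rgs1, Clec4b1 and Bcl2a1c were not well above background on any control array, with bounds of 54.2-, 43.0-, 18.0- and 17.6-fold (5.76, 5.43, 4.17 and 4.14 on the log2 scale). The normexp values of these genes, given below, lie under their bounds. By their bounds the places of Clec4b1 and Bcl2a1c among the 12 are not settled. Ms4a7, C1qa, Ccl4 and Ms4a6d were above background on 1 of the 3 control arrays and Fpr2 on 2. For these dim genes normexp correction gave smaller fold changes, among them 3.57 for Adamdec1, 3.44 for Rgs1, 3.41 for Fpr2, 3.04 for Ccl4, 2.19 for Clec4b1 and 2.16 for Bcl2a1c, all past the test.

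Of all changed genes Erdr1, a gene of the pseudoautosomal region shared by X and Y, fell the furthest. It fell by 8.37 on the log2 scale (SE 0.60, adjusted p = 0.000754), with values of 5.88, 5.76 and 6.12 on the control arrays and -0.94, -3.39 and -3.02 on the Yaa arrays. Its probe shares 25 bases with that of the unnamed transcript TC1700876, which had a fold change of -8.29. The next named falls were far smaller: Acsl6, an acyl-CoA synthetase, had a fold change of -2.04 ± 0.40, Lypd1 -1.86 ± 0.25, Cnmd (named Lect1 on the array) -1.80 ± 0.29, the thyrotropin receptor Tshr -1.71 ± 0.25, R3hdml -1.60 ± 0.25 and Syt15 -1.59 ± 0.22. Ntm (-1.58 ± 0.32), the fatty acid elongase Elovl4 (-1.47 ± 0.27), Tmem182 (-1.44 ± 0.21), Wnt10a (-1.43 ± 0.19) and Dusp19 (-1.32 ± 0.22) fell as well. Acsl6 was not well above background on any Yaa array, with a bound of 3.76-fold for its fall (-1.91 on the log2 scale). Tshr, Ntm, Elovl4 and Dusp19 were above background on 1 of the 3 Yaa arrays and Wnt10a on 2. With the replicate block the adjusted p was 0.0577 for Cnmd, 0.0610 for Acsl6, 0.0826 for Dusp19, 0.0946 for Elovl4 and 0.0946 for Ntm, and normexp correction ended 7 calls with smaller fold changes: Acsl6 at -0.60 (adjusted p = 0.135), Elovl4 at -0.34 (0.274), Dusp19 at -0.44 (0.188), Ntm at -0.52 (0.0586), Tshr at -0.63 (0.0594), Tmem182 at -0.74 (0.0604) and Wnt10a at -0.67 (0.0533). Quantile normalization gave adjusted p = 0.121 for Elovl4 and 0.129 for Ntm, and an intensity trend with robust variances gave 0.0610 for Elovl4, 0.0574 for Ntm and 0.0523 for Dusp19. With no filter on dim probes, Erdr1, Lypd1 and Wnt10a were the ones of these 12 falls that passed.

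Of 20716 genes tested with limma, 790 passed an adjusted p of 0.05, 614 of them higher and 176 lower in Yaa glomeruli, and 632 of these differed at least 2-fold (555 higher, 77 lower). At an unadjusted p under 0.05 there were 3333 genes. The groups did not overlap for 25.2% of all genes, where chance gives 10%. Among the 790 genes, 97 were not well above background on any control array and 5 on any Yaa array. For 151 the array's name is an accession, a clone, a predicted gene, a LOC name or a receptor segment, though some of these have a current symbol. The median fold change of all genes was -0.11. With the replicate number as a block 98 genes were lower and 618 changed in all. Without control replicate 1, 2 or 3 the number of lower genes was 25, 21 or 30, and without Yaa replicate 1, which lies apart from the other Yaa arrays on the second principal component (-53.6 against 9.34 and 25.6), it was 366. On the first component, with 59.3% of the variance against 18.2% for the second, Yaa replicate 3 lies apart (71.4 against 25.5 and 33.5). Without Yaa replicate 2 or 3 the number of lower genes was 105 or 73. Leaving out each array in turn gave 395 to 1027 changed genes, 365 to 661 higher ones and 388 to 766 changed at least 2-fold.

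Among the Toll-like receptors, the innate sensors of microbial and nucleic acid ligands, 6 of 9 measured members rose, none fell and 3 did not pass. Tlr1 rose by 3.04 ± 0.25, Tlr13, a receptor for bacterial ribosomal RNA, by 2.37 ± 0.17, Tlr2 by 1.57 ± 0.17 and Tlr6 by 1.42 ± 0.18, beside Tlr7 and Tlr8. Tlr4 was at 0.76 ± 0.27 (adjusted p = 0.226), Tlr12 at 0.15 ± 0.21 and Tlr9, a receptor for DNA, at -0.07 ± 0.14. Tlr3 (above background on 1 control and 2 Yaa arrays), Tlr11 (on 1 Yaa array) and Tlr5 (on none) were above it on too few arrays to be tested. Macrophage markers, described with the other leukocyte genes, had a median of 3.24 on the same arrays. Adjusted over the list alone 7 members were higher. The list's median was 1.42 (camera adjusted p = 3.34e-12, and adjusted p = 0.103 with an estimated correlation), and 0.89 with normexp correction and 0.86 with no filter on dim probes. Of 16 adaptors and signalling genes of these receptors 5 rose, none fell and 11 did not pass, and 6 were higher adjusted over the list alone. The transcription factor Irf5 rose by 2.71 ± 0.24, the transport protein Unc93b1 by 1.42 ± 0.18, and the cytokines Tnf and Il1b by 3.57 ± 0.34 and 2.47 ± 0.35. Tnf was not well above background on any control array (bound 3.96-fold, 1.99 on the log2 scale), but normexp correction gave it a log2 fold change of 0.75. The adjusted p of Il1b was 0.0630 with the block and 0.0544 with no filter. The median of this list was 0.12 and its mean 0.85 (camera adjusted p = 2.52e-06, and adjusted p = 0.114 with an estimated correlation). This median was 0.29 with the mean of a gene's probes, 0.19 without control replicate 1 and 0.20, 0.19 and 0.21 without Yaa replicates 1, 2 and 3.

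Interferon-stimulated genes had a median fold change of 1.61, and 9 of 29 rose, none fell and 20 did not pass. Ifi27l2a rose by 2.96 ± 0.23, and 3 genes of the oligoadenylate synthetase family of antiviral proteins rose as well: Oas2 by 3.90 ± 0.44, Oas1a by 2.28 ± 0.26 and Oasl1 by 1.61 ± 0.19. Adjusted over the list alone 19 were higher, and camera gave an adjusted p = 2.66e-23, with adjusted p = 0.178 with an estimated correlation. In the antigen presentation list 6 of 17 genes rose, none fell and 11 did not pass, with 16 higher adjusted over the list alone. The invariant chain Cd74 rose by 2.91 ± 0.23, the class II genes H2-Eb1 and H2-Ab1 by 3.47 ± 0.32 and 3.04 ± 0.32, and the costimulatory molecule Cd86, above background on 1 of the 3 control arrays, by 4.05 ± 0.43. The list's median was 1.86 (camera adjusted p = 2.67e-18, and adjusted p = 0.144 with an estimated correlation), and 1.18 without Yaa replicate 3. These arrays are the ones on which macrophage markers had a median of 3.24.

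Macrophage markers made up the list with the highest median, 3.24, or 3.21 with genes below background taken at their bound and 2.16 with normexp correction. Of 17 measured markers 14 rose, none fell and 3 did not pass, and the count was also 14 adjusted over the list alone. Adgre1, which encodes the antigen F4/80 and is named Emr1 on the array, rose by 4.65 ± 0.20, the CSF1 receptor gene Csf1r by 2.13 ± 0.13 and Mpeg1 by 3.92 ± 0.27, beside Ms4a7. Camera gave an adjusted p = 6.90e-26, with adjusted p = 0.0649 with an estimated correlation. Among T cell markers 0 of 11 passed limma's test, and none passed adjusted over the list alone, although the median was 0.95 (camera adjusted p = 0.000463, and adjusted p = 0.266 with an estimated correlation) and 0.56 without Yaa replicate 3. At an unadjusted p under 0.05 Cd3g (2.01 ± 0.81), Cd5 (1.96 ± 0.73) and Gzmb (2.00 ± 0.65) were counted. Their values were spread across the Yaa arrays, with Cd3g at -1.79, -2.96 and 0.60 on Yaa replicates 1 to 3 and at -3.47, -3.14 and -3.58 on the control arrays, and Cd3d stood at 1.68 ± 0.84.

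Among B cell and plasma cell markers 1 of 12 rose, none fell and 11 did not pass. It was Jchain, the joining chain of secreted immunoglobulin (named Igj on the array), at 1.87 ± 0.32, with an adjusted p of 0.0651 with the block and 0.0996 with no filter on dim probes. Blnk was at 0.80 ± 0.17 (adjusted p = 0.0610), Cd79b at 0.92 ± 0.29 and Sdc1 at -0.55 ± 0.17, and 3 markers were higher and 1 lower adjusted over the list alone. The median was 0.31 (camera adjusted p = 0.0139, and adjusted p = 0.382 with an estimated correlation), and the camera call was lost without Yaa replicate 1 (0.237) or control replicate 3 (0.0620). This median was 0.17 with normexp correction, 0.13, 0.84 and 0.15 without Yaa replicates 1, 2 and 3, and 0.48 and 0.12 without control replicates 1 and 3. None of the 9 neutrophil markers passed, and none did adjusted over the list alone. Ly6g was at 1.01 ± 0.50, Camp at 0.56 ± 0.37, Cxcr2 at -0.37 ± 0.37 and Csf3r at -0.15 ± 0.20, and the list had a median of -0.02, a mean of 0.14 and a camera adjusted p of 0.316 in the higher direction, which became 0.0224 without Yaa replicate 2. Of the 9 erythroid and platelet markers none passed, with 1 higher adjusted over the list alone. Itga2b was at 0.90 ± 0.22, Pf4 at 0.63 ± 0.24, Alas2 at -0.31 ± 0.26 and Ppbp at 0.26 ± 0.28. The list's median was 0.08, with a camera adjusted p of 0.0681, and 0.0366 with the replicate block. Without control replicate 1 this camera adjusted p was 0.0470, without Yaa replicate 2 it was 0.00197 and without Yaa replicate 3 it was 0.728.

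Genes of complement, Fc receptors and leukocyte recruitment were higher in Yaa glomeruli as well, beside the macrophage median of 3.24. In the complement list 8 of 17 rose, none fell and 9 did not pass, with 11 higher adjusted over the list alone. The receptors C3ar1 and C5ar1 rose by 2.87 ± 0.13 and 3.99 ± 0.21, beside the C1q genes. C5ar1 was not well above background on any control array (bound 5.02-fold, 2.33 on the log2 scale) and C3ar1 was above it on 2. With normexp correction C3ar1 was at 1.14 and C5ar1 at 1.07. The median was 1.33 (camera adjusted p = 6.19e-16, and adjusted p = 0.124 with an estimated correlation). Of 7 Fc receptor genes 5 rose, none fell and 2 did not pass, and 7 were higher adjusted over the list alone. Fcer1g, the shared signalling chain, rose by 3.78 ± 0.22, the inhibitory receptor Fcgr2b by 2.39 ± 0.27 and the high-affinity receptor Fcgr1 by 3.85 ± 0.51, these 2 above background on 2 and 1 of the control arrays. The median was 2.92 (camera adjusted p = 8e-13, and adjusted p = 0.0843 with an estimated correlation), and 1.18 with normexp correction. Among chemokines 6 of 16 rose, none fell and 10 did not pass, with 11 higher adjusted over the list alone and a median of 2.32 (camera adjusted p = 1.99e-13, and adjusted p = 0.0649 with an estimated correlation). Ccl9 rose by 2.42 ± 0.19, the monocyte attractant Ccl2 by 4.72 ± 0.57 and Ccl3 by 4.38 ± 0.55. Ccl2 was above background on 1 control array and Ccl3 on none (bound 13.7-fold, 3.77 on the log2 scale), and the block gave Ccl3 an adjusted p of 0.0503. With normexp correction Ccl2 was at 2.34 and Ccl3 at 1.89. Of 10 adhesion molecules of leukocyte recruitment 5 rose, none fell and 5 did not pass, with 6 higher adjusted over the list alone and a median of 1.75 (camera adjusted p = 3.34e-08, and adjusted p = 0.0843 with an estimated correlation), which was 1.05 with normexp correction. The integrin genes Itgb2 and Itgal rose by 3.37 ± 0.27 and 2.30 ± 0.24, the selectin ligand Selplg by 2.76 ± 0.18 and the endothelial selectin Sele, above background on 1 control array, by 2.64 ± 0.27.

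**Figure D2:**
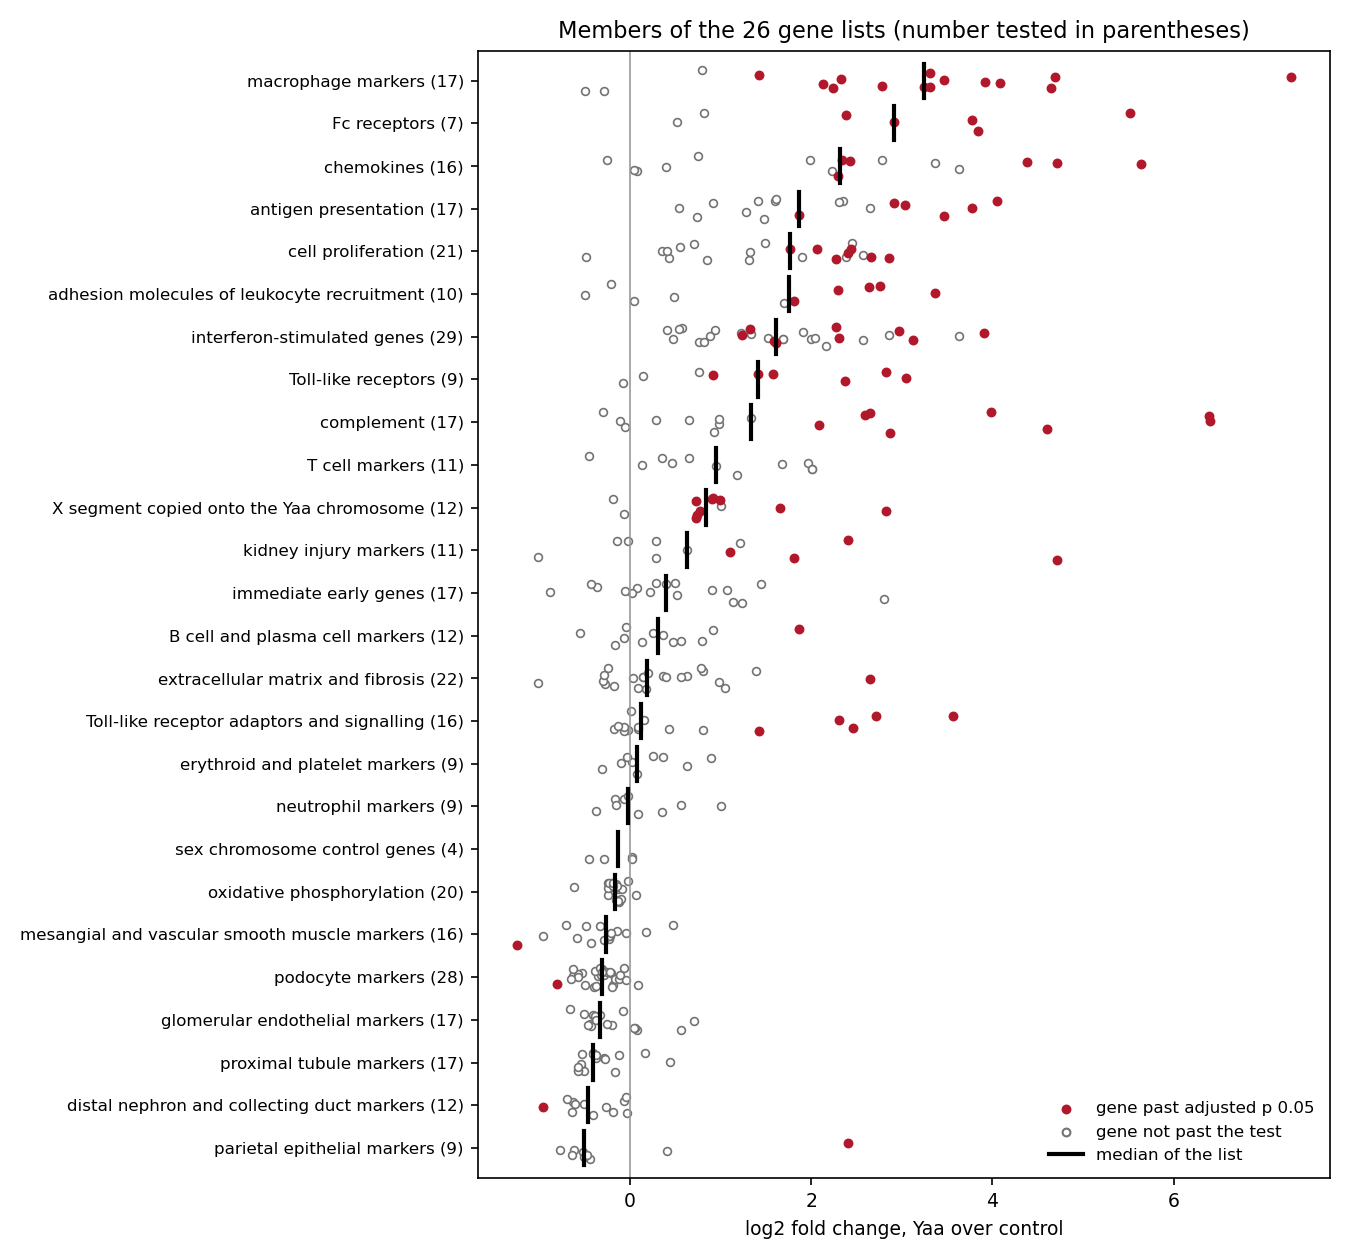
Log2 fold change (Yaa over control, n = 3 arrays per group) of each measured member of the 26 gene lists, 1 list per line ordered by its median, with red points past an adjusted p of 0.05, open points not past it and a bar at the median. Macrophage markers have the highest median (3.24) and parietal epithelial markers the lowest (-0.51); podocyte markers have a median of -0.31 with 1 gene past the test.

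Podocyte markers, genes of the epithelial cells that wrap the glomerular capillaries, had a median fold change of -0.31, and 1 of 28 fell, none rose and 27 did not pass. The gene that fell was Thsd7a, at -0.80 ± 0.15 (adjusted p = 0.0334, 0.0556 with quantile normalization and 0.144 with no filter on dim probes), from 5.60 ± 0.09 to 4.80 ± 0.20 (log2 signal, SD). Plce1 was at -0.57 ± 0.13 (adjusted p = 0.0675), Nes at -0.53 ± 0.12 and Trpc6 at -0.58 ± 0.14. Synpo, a gene of the podocyte's actin cytoskeleton, was at -0.35 ± 0.19 (adjusted p = 0.419) and Podxl at -0.18 ± 0.15. A dimmer probe of each, above background on all 3 arrays of both groups, differed by -0.87 for Synpo and -0.56 for Podxl. The Nphs1 probe was above background on 1 array of each group and was not tested. The macrophage markers, at 3.24, lay on the other side of 0. Adjusted over the list alone 5 markers were lower, and camera gave an adjusted p = 6.79e-05, with adjusted p = 0.245 with an estimated correlation. Of 16 mesangial and vascular smooth muscle markers 1 fell, none rose and 15 did not pass, with 2 lower adjusted over the list alone. The gene that fell was Sfrp1, a secreted Wnt antagonist, at -1.24 ± 0.21 (adjusted p = 0.104 with no filter), while Cspg4 was at -0.95 ± 0.23, Ren1 at -0.70 ± 0.24 and Notch3 at -0.48 ± 0.17. This list's median was -0.26 (camera adjusted p = 0.0302, and adjusted p = 0.409 with an estimated correlation), and the call was lost without Yaa replicate 1 (0.247) or control replicate 3 (0.0541). Without Yaa replicate 2 the median was -0.43.

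None of the 17 glomerular endothelial markers passed, and none did adjusted over the list alone (median -0.33, camera adjusted p = 0.239, and median -0.18 without Yaa replicate 3). Their members went both ways, with Plvap at 0.71 ± 0.18 (adjusted p = 0.0913), Flt1 at -0.50 ± 0.13, Esam at -0.38 ± 0.13 and Kdr at -0.66 ± 0.24. Of the 9 parietal epithelial markers 1 rose, none fell and 8 did not pass, with 1 higher and 5 lower adjusted over the list alone. The gene that rose was Cd44, a hyaluronan receptor that leukocytes also express, by 2.40 ± 0.24, while Scin was at -0.77 ± 0.19, Krt18 at -0.64 ± 0.16 and Pax8 at -0.61 ± 0.15 (median -0.51, camera adjusted p = 0.0681). Markers of tubule segments were measurable too. Of 17 proximal tubule markers none passed and 1 was lower adjusted over the list alone. Gatm was at -0.57 ± 0.12, Aqp1 at -0.51 ± 0.22, Slc22a12 at -0.54 ± 0.31 and Slc5a2 at -0.54 ± 0.33 (median -0.41, camera adjusted p = 0.124, which was 0.0210 without control replicate 3, 0.00486 without Yaa replicate 2 and 0.0233 without Yaa replicate 3, while the median was -0.20 (0.734) without control replicate 1 and -0.06 (0.434) without Yaa replicate 1). Of 12 distal nephron and collecting duct markers 1 fell, none rose and 11 did not pass, with 5 lower adjusted over the list alone. It was the sodium-potassium-chloride cotransporter Slc12a1, at -0.96 ± 0.16 (adjusted p = 0.117 with no filter), while Fxyd2 was at -0.64 ± 0.18, Umod at -0.51 ± 0.15 and Cdh16 at -0.62 ± 0.19. The list's median was -0.46 (camera adjusted p = 0.0137, and adjusted p = 0.382 with an estimated correlation), and without Yaa replicate 1 it was -0.24 (camera adjusted p = 0.237). Of 20 oxidative phosphorylation genes none passed, also adjusted over the list alone, with Ppargc1a at -0.61 ± 0.13, Uqcrc2 at -0.24 ± 0.12 and Ndufb3 at -0.22 ± 0.12 (median -0.16, camera adjusted p = 0.0707, and 0.0260 with no filter on dim probes, 0.0370 without Yaa replicate 2 and 0.00411 without Yaa replicate 3, while without Yaa replicate 1 the median was -0.05 and this p 0.966).

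Genes of cell proliferation had a median fold change of 1.77, or 1.49 with genes below background taken at their bound and 1.01 with normexp correction. Macrophage markers had a median of 3.24 on these arrays, as they had beside the injury and matrix genes below. Of 21 measured 7 rose, none fell and 14 did not pass, with 15 higher adjusted over the list alone. The proliferation antigen Mki67 rose by 2.67 ± 0.49, Birc5 by 2.86 ± 0.56, the ribonucleotide reductase gene Rrm2 by 2.40 ± 0.46 and the cyclin gene Ccna2 by 2.44 ± 0.48. Camera gave an adjusted p = 6.60e-16, with adjusted p = 0.144 with an estimated correlation. The block gave adjusted p = 0.0526 for Rrm2, 0.0552 for Birc5 and 0.0582 for Ccna2, normexp correction gave Ccna2 0.0564, and with no filter on dim probes none of these 4 passed (0.119 to 0.147). Among kidney injury markers 4 of 11 rose, none fell and 7 did not pass, with 5 higher and 1 lower adjusted over the list alone. Besides Cd44 and Ccl2 these were Hmox1, the stress-induced heme oxygenase, by 1.10 ± 0.21 and the adhesion molecule Vcam1 by 1.81 ± 0.36, with a blocked adjusted p of 0.0827 for Vcam1 and, with the mean of a gene's probes, 0.0703 for Hmox1, and with no filter 0.157 for Vcam1 and 0.139 for Hmox1. The median was 0.63 (camera adjusted p = 6.33e-06, and adjusted p = 0.144 with an estimated correlation), and 0.38 with normexp correction. Of 22 extracellular matrix and fibrosis genes 1 rose, none fell and 21 did not pass, and 1 was higher adjusted over the list alone. It was Tgfbi, by 2.65 ± 0.42 (adjusted p = 0.0735 with no filter), while Col6a3 was at 0.81 ± 0.21 and Mmp2 at 0.78 ± 0.23 (median 0.19, camera adjusted p = 0.000463, and adjusted p = 0.301 with an estimated correlation). This median was 0.29 without control replicate 3 and 0.36, 0.05 and 0.34 without Yaa replicates 1, 2 and 3.

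None of the 17 immediate early genes passed and 1 was higher adjusted over the list alone. Egr2, not well above background on any control array, was at 2.80 ± 0.58 (adjusted p = 0.0527, bound 4.57-fold), Nr4a1 at 0.91 ± 0.35, Jund at -0.43 ± 0.17 and Jun at -0.37 ± 0.16. The median was 0.39 (camera adjusted p = 0.00434, and adjusted p = 0.382 with an estimated correlation), and the camera call was lost without Yaa replicate 3 (0.0681). Without Yaa replicate 1 the median was 0.60 and without Yaa replicate 3 it was 0.02. Of the 4 measured sex chromosome control genes none passed, also adjusted over the list alone. The Y-linked Uty was at -0.29 ± 0.17, Kdm5d, above background on 1 of the 3 Yaa arrays, at -0.46 ± 0.30, Ddx3y at 0.02 ± 0.14 and Eif2s3y at 0.03 ± 0.19 (median -0.13, camera adjusted p = 0.723). Over the 26 lists camera called 16 higher and 3 lower, and none of these 19 calls held with an estimated correlation, where the smallest adjusted p was 0.0649.

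**Figure D3:**
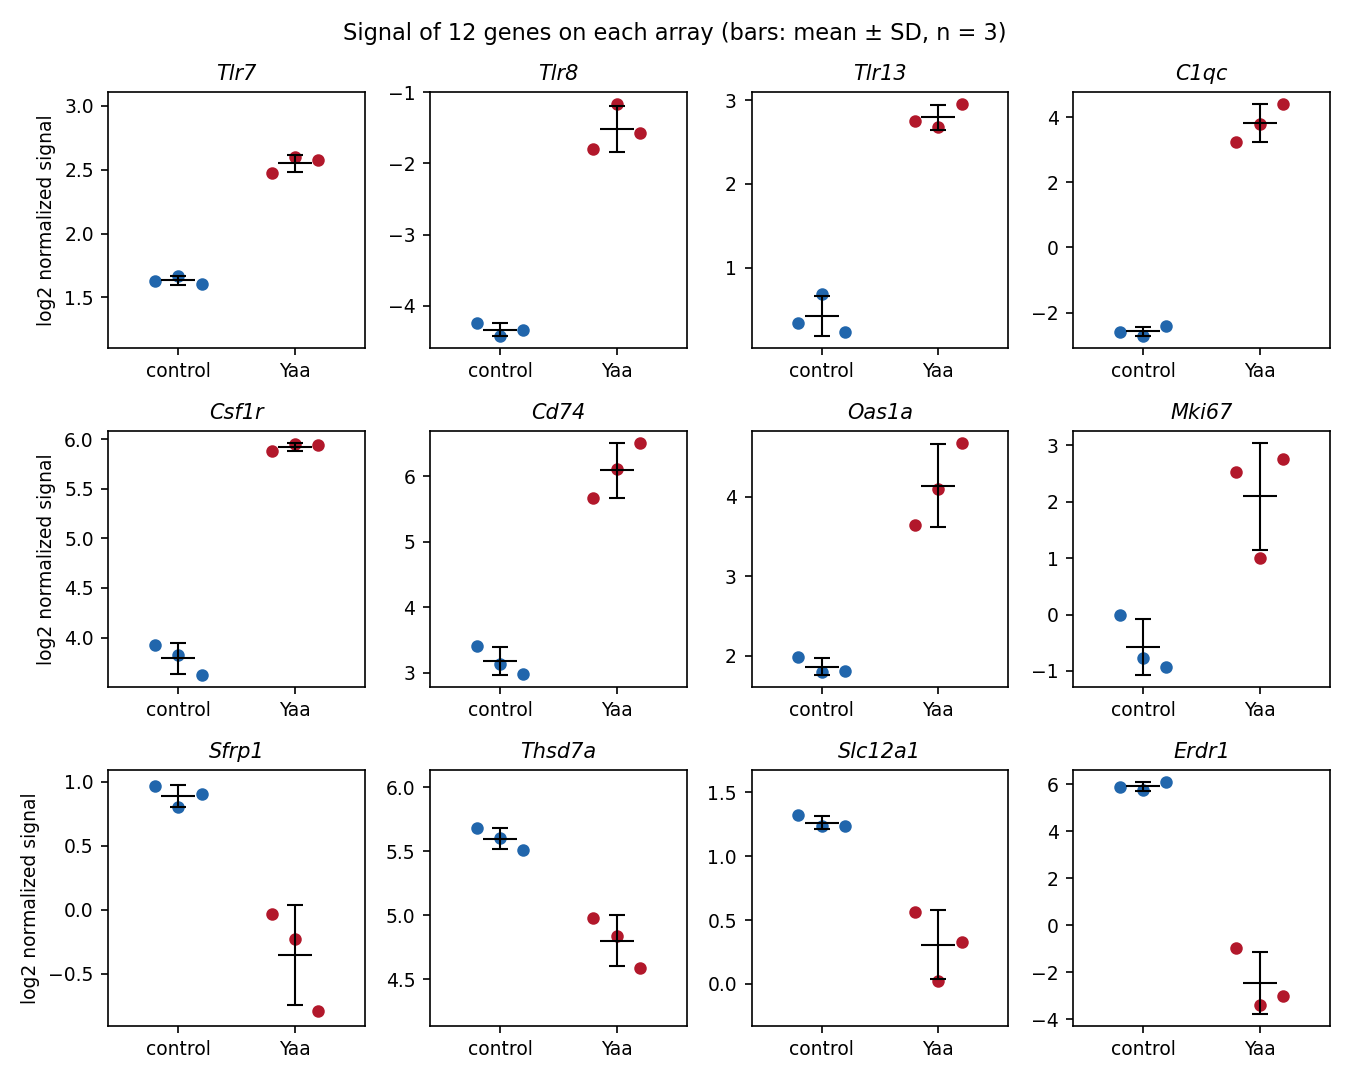
Log2 normalized signal of 12 genes on each array (blue, control; red, Yaa), with the mean and SD of each group of 3 arrays and a separate vertical scale in each panel. The 3 Yaa arrays lie above the 3 control arrays for Tlr7, Tlr8, Tlr13, C1qc, Csf1r, Cd74, Oas1a and Mki67 and below them for Thsd7a, Slc12a1, Erdr1 and Sfrp1.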

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

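Every alternative in this part was planned. The calls changed with the arrays used and with the filter on dim probes. The 790 changed genes were 396 with no filter on dim probes (34844 genes tested), 371 at an adjusted p of 0.01 and 395 to 1027 without each array in turn. The 614 higher genes were 375, 353 and 365 to 661 under these settings, the 176 lower ones 21, 18 and 21 to 366, and the 632 genes changed at least 2-fold 394, 363 and 388 to 766, with 416 after normexp correction. The replicate block gave 98 lower genes and 618 in all, of which 545 were among the 790. Higher genes made up 77.7% of the calls, and 94.7% with no filter, 94.3%, 94.9% and 92.4% without control replicates 1, 2 and 3, and 64.4% and 88.0% without Yaa replicates 1 and 3. Leaving out an array lowers the number of arrays alike each time. Yet the changed genes were 436, 408 and 395 without control replicates 1, 2 and 3, and 1027, 686 and 608 without Yaa replicates 1, 2 and 3. The number of arrays alone therefore does not account for these counts, and the cause of these and of the other moves was not tested. The median of all genes, -0.11, lay between -0.13 and -0.06 under every setting, so that quantile normalization (-0.08) or centring moved it by less than 0.1.

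With an estimated correlation none of the 26 lists was called, 0 higher and 0 lower against 16 and 3. The medians stay as they were by construction, with adjusted p = 0.0649 for the X segment (0.84), 0.103 for Toll-like receptors (1.42), 0.178 for interferon-stimulated genes (1.61), 0.0649 for macrophage markers (3.24) and 0.245 for podocyte markers (-0.31), and these 5 kept their call in each of their other 15 settings. No list changed its call or direction with quantile normalization, median centring or normexp, but normexp lowered the medians of 7 called lists and of the genes within 5 Mb of the X end by over 1.5 times, as given above, and 34 of the fold changes of the 76 named genes past the test. The genes within 5 Mb of the X end kept their call in all 16, with a median of 0.21 against 0.74 after normexp. Without each array in turn 1 to 5 lists were lower. The block changed 1 list's call, that of erythroid and platelet markers (0.0366), and 17 calls among the named genes, each given above, and no other. Of 76 named genes past the test, 46 passed it without each array in turn, 59 with the block, 66 after normexp and 47 with no filter. Leaving out control replicate 1, 2 or 3 ended 24, 27 or 26 of these calls, and Yaa replicate 1, 2 or 3 ended 4, 17 or 17, and 1 of the 9 X segment genes, Tlr8, passed without each array in turn, and the same 1 with no filter.

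Signs turned in lists and genes that did not pass the test. The neutrophil median (-0.02) was 0.0905 with no filter and ran from -0.29 to 0.59 without each array in turn, the erythroid one (0.08) from -0.12 to 0.36, and the sex chromosome genes (-0.13) had 0.0225 with probes above background on all 6 arrays. Without each array in turn Ofd1 ran from -0.15 to 0.0191, Tlr12 from -0.0414 to 0.24, Cxcr2 from -0.70 to 0.0249, Ddx3y from -0.073 to 0.11 and Eif2s3y from -0.14 to 0.18. A slide or scan block was not run, since all arrays share 1 slide and 1 scan, and the slide column goes with the strain.

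Other splits of the 6 arrays into 3 and 3 number 9, too few for a share under 0.05. They gave at most 0 genes changed, 0 higher, 0 lower and 0 changed at least 2-fold, against 790, 614, 176 and 632, so that 1 of 10 splits, the real one, reached each count. Each of these other splits mixes both strains on each side, which puts the strain difference into the spread within sides and favours few calls. The sides also hold unequal numbers of Yaa arrays, so that part of the strain difference stays between them. Neither their 0 genes nor their list counts therefore show what chance alone gives. For lists called by camera the real split gave 19, the highest other 20, and 3 of the 10 splits reached 19. The other splits that part all 3 pairs gave 0 genes and 19, 20 and 11 lists.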

Other observations

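Gene families were compared after the results had been seen, by counting past-threshold genes among 12397 genes with a symbol stem (Fisher's exact test, one-sided, adjusted over 850 tests of 425 stems). The test counts genes as independent. Its p-values allow neither for genes that vary together nor for the number of arrays. C-type lectins, receptors of myeloid cells and natural killer cells, had 10 of 21 members higher and none lower (adjusted p = 4.42e-07), of which Clec7a is also a listed macrophage marker and 9 are in no list, among them Clec4b1, Clec4a3 at 4.12 ± 0.38, Clec4e at 4.06 ± 0.36 and Clec4a1 at 3.79 ± 0.19 (log2 fold change ± SE, n = 3 arrays per group). GTPase-activating proteins of the Arhgap stem had 8 of 29 higher and none lower (adjusted p = 0.000880, and 7 of the 8 after normexp correction) with a stem median of 0.10. Of these 8, Arhgap6 is a listed X segment gene and 7 are in no list. The Tlr, Ifi, Ccl and Oas stems passed too, each with members in the lists above. Orphan and other G protein-coupled receptors of the Gpr stem had 7 of 34 higher (adjusted p = 0.0184; 4 of the 7 after normexp correction) with a stem median of -0.12. Gpr84, a receptor of activated myeloid cells, was at 4.78 ± 0.27 and not well above background on any control array, with a bound of 9.20-fold, and Gpr65, a proton-sensing receptor, was at 3.98 ± 0.30. Synaptotagmins went the other way, with 3 of 12 lower, Syt1, Syt5 and Syt15, and none higher (adjusted p = 0.0281), of which 1 passed the test after normexp correction. Of further genes picked after their values were seen, the integrin genes Itgax and Itgad were at 4.36 ± 0.26 and 5.10 ± 0.41, Acod1, which makes itaconate in activated macrophages, at 5.12 ± 0.28, and Spic, a transcription factor of red pulp macrophages, at 5.19 ± 0.28. Among lower genes, the transcription factor genes Irx1 and Irx2 were at -1.10 ± 0.14 and -1.16 ± 0.21, the notch target Hey2 at -1.19 ± 0.17 and the growth factor gene Hbegf at -1.12 ± 0.18.

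On chromosome X (mm9), between 120353972 and 122630826 and so outside the copied segment, 7 intervals without a gene name, picked after their values were seen, had fold changes of 3.95 to 5.75, and 6 of these 7 passed the test. They were 7 of the 13 unnamed intervals tested with probes starting from 120134828 to 122630319, and the other 6 had fold changes of -0.54 to 0.52, none past the test (smallest adjusted p = 0.0899). Of the 7 intervals 6 were not well above background on any control array, with bounds of 9.08-fold to 21.6-fold, and 15 of 21 pairs of their probes share 12 or more bases, up to 57.

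The tests below were all chosen after the results were seen. Podocyte and mesangial markers had medians of -0.31 and -0.26. Fewer tubule fragments would leave podocyte markers at or above 0, and the 95% bootstrap interval of the median of -0.31 ended at -0.22. Without each array in turn this median ran from -0.39 to -0.25. Scaling to the 75th percentile would put these markers at the median of all genes, and they lay -0.20 from it (-0.28 to -0.10). The bootstrap intervals resample the genes of a list with the arrays held fixed. They do not measure the spread between pools, so they set neither explanation aside. Dilution by leukocyte RNA, which would lower every resident cell type alike, remains open, since among the medians of the 5 podocyte, mesangial, endothelial, proximal tubule and distal nephron lists the largest difference was 0.197 (interval -0.22 to 0.40), although the proximal tubule median was -0.06 without Yaa replicate 1 and the endothelial one -0.18 without Yaa replicate 3. Loss of podocyte transcripts with the nephritis itself stays open too and was not tested.

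Tlr8 rose by 2.82, more than any other gene of the X segment. An extra copy of the segment alone would put the control signal 1 below the Yaa signal on the log2 scale. There 100% of probes were well above background on each control array (counted from the dimmest Yaa array), yet neither Tlr8 probe was on any of them. Both probes were thus dimmer on the control arrays than a doubling predicts, which argues against the copy alone. Being above background depends on the signal itself, so it is not separate evidence. Normexp correction gave 0.89 ± 0.13 and 1.42 ± 0.18 for the 2 probes. It gave at most 0.64 and 0.67 for the 25 and 27 probes as bright with a fold change within 0.15 of 1 before it. Given its SE, the 0.89 is not clearly apart from the 0.64. RNA of macrophages, which express this receptor, stays open beside the copy, as the 10th and 90th percentile of the macrophage markers, 0.36 and 4.67, hold 1 and 2.82 alike and decide nothing. They hold the 0.91 of Tlr7 too, for which the extra copy and macrophage RNA cannot be told apart with these values.

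Erdr1 fell by 8.37. Dilution by RNA of other cells would give a fall like those of the 5 resident lists compared above, whose lowest median was -0.46. The parietal epithelial list, not among these 5, had a median of -0.51. The 95% interval of Erdr1 ended at -6.94. The only other probe that fell alike, of the unnamed transcript TC1700876 (-8.29), shares a stretch of 25 of its 60 bases with the Erdr1 probe, so that a sequence variant under both probes and a lower transcript level cannot be told apart with these probes. The strains differ in their Y chromosome, whose pseudoautosomal end may carry another copy or allele of Erdr1, which was not tested.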
